A study of Saccharomyces cerevisiae with 78 samples.

How the data were processed

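The samples were chromatin immunoprecipitates and input DNA of budding yeast, *Saccharomyces cerevisiae*, sequenced as multiplexed Illumina libraries (ChIP-seq). Of 78 samples, 49 were immunoprecipitates and 29 were inputs. Per the labels' protocols, cells were grown for 48 h at 30 °C to saturation and growth arrest, in dextrose medium for the tag-switch strain and in galactose medium for the strain overexpressing Sir3. For the latter the growth protocol also gives a starvation longer than the 48 h in the label of its starved library, and which applies was not settled. In the tag-switch strain, estradiol was then added for 16 h to switch the epitope on Sir3 from HA to T7, and cells were released into fresh medium. Per the labels' protocols, aliquots were fixed in 1% formaldehyde, cell walls were broken by bead beating, chromatin was sonicated, and libraries carried custom inline barcodes.

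The values used were scores in 10-bp bins, deposited by the authors in 3 tables, 1 for each tag-switch time course and 1 for the overexpression strain. Per the file headers, each of the 1207087 bins has a chromosome, a position and the features that overlap it. Base calls were made with CASAVA 1.7.0, per the submitters' processing notes. The aligner, the read extension and the genome build are not given in the sources used here. The scale of the deposited scores was worked out from the values. In most bins a score is the log2 ratio of immunoprecipitate to input, each relative to its own genome average. In the tag-switch tables, bins where the anti-HA or the anti-T7 value of a sampling point is exactly 0 hold linear levels that were not divided by input. Log2 bins were therefore raised to the power of 2 and linear bins were taken as they stand. In the overexpression table, a score of exactly 0 was also taken as a linear level of 0 and not as a log2 ratio. Such bins made up 7.74% of the library after 1 h in dextrose and 0.954% of that after 1 h in galactose. The planned design assumed linear values throughout, and the conversion was added once the mixed scale was seen. No value was given for 5.41% to 6.25% of bins per library, and for 10.3% in the second run of the first-course libraries taken before the switch. The share of bins at exactly 0 had a median of 0.411% over libraries, and reached 53.8% in the anti-HA library taken 30 min after release in the first course. The tables hold no read counts, so the sequencing depth is unknown.

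The 3 tables hold 63 value columns, of which 51 were matched to samples by name and used and 12 were not used. The 29 inputs enter only through the ratios and were not analysed here on their own. The 2 runs of the first-course libraries taken before the switch were averaged and counted as 1 replicate. Gene names were taken from the RefSeq R64 table by systematic name, without its coordinates. Of 6531 open reading frames in the tables, 5877 matched a name and 5874 were protein-coding. The tables annotate 365 of the genes over less than 300 bp, in some cases only a stretch of the gene. Positions are those of the tables.

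For each library, the value of a gene was the mean of its bins, where at least 80% of them had a value, divided by the median over genes of that library. Values below are given as multiples of this median gene. Log2 changes are on the scale of log2(value + 0.1), which understates changes of low values. Tests were made with limma 3.58.1 in R 4.3.3 (linear model per gene with moderated variances, two-sided, Benjamini-Hochberg adjusted p under 0.05). The tag-switch model held 26 libraries of 12 groups (2 tags at 6 sampling points that both courses share), with the time course as a term for each tag. The tables were normalized separately, so only differences within a table entered the tests. The overexpression model held 8 libraries with sampling point and sugar as terms. Each sugar had 1 library per point, with galactose and dextrose at 3 points and raffinose at 2, so the spread there is what the additive model left over. The groups of the tag-switch model hold 2 libraries each, 1 per course, or 3 at 2 doublings. The labels name no separate cultures within a course, so p-values measure the spread between these libraries. The numbering of replicates follows the time course, which the labels give, and the course was a block in the model. For the pairing check, the first-minus-second course difference was correlated over genes between the 15 pairs of groups of a tag. The correlation had a median of 0.255 for anti-HA, from 0.0229 to 0.560, and of 0.392 for anti-T7, from -0.0490 to 0.656.

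Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, and again with an estimated correlation, with Benjamini-Hochberg adjustment over 188 tests of 19 lists. The lists were ribosomal protein, ribosome biogenesis, glycolysis and fermentation, stress and stationary phase, respiration and tricarboxylic acid cycle, galactose, hexose transport, PAU, COS, flocculin, histone, cell cycle entry, mating, SIR, tRNA and highly transcribed genes, and genes 0 to 10 kb, 10 to 20 kb and 20 to 30 kb from a chromosome end. A list of the genes at the silent mating loci HML and HMR had 0 members in the tables. The silencers ARS301 and ARS302 of HML and ARS317 and ARS318 of HMR were taken in their place, a choice made after this was seen. Members of the PAU and COS families and other subtelomeric genes have near-identical copies that share reads, and their values are uncertain. Genes named in the report follow a rule fixed before the data were examined, together with the lists, the tests and the first set of other settings. It takes the 8 largest rises and the 8 largest falls among genes that passed with the same sign in both courses, or at every time point for the overexpression strain. Where none passed, it takes the 5 genes with the smallest p as values only. It adds the galactose, SIR and histone genes and up to 4 members with the largest changes of any other list described.

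The median value of genes within 10 kb of a chromosome end was correlated with the number of doublings per tag and course, with exact permutation below 10 libraries and 100000 resamples otherwise, over 4 relations. Values of X elements, silencers and other annotated features, the profile in 1 kb windows from the chromosome ends, and the reach of signal from each end (consecutive windows of at least 2 times the median gene) were computed in the same scaling. The reach passed over windows without a value, so a run can span them. Summaries used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

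The model was tested on simulated data in which 200 genes were changed by a known log2 amount. Each gene had its own residual spread, equal in all libraries and independent of other genes. For anti-HA 30 min after release, over 5585 genes, 33% of changes of 1, 93% of changes of 2 and 99.5% of changes of 4 were recovered. For anti-HA at 4 doublings the shares were 26%, 87% and 99.5%. For galactose against dextrose, over 5654 genes, they were 0%, 81.5% and 98%. The simulation held no unequal noise of libraries, course effect, bins at 0 or sugar difference that grows with time. The shares do not carry over to comparisons where these occur, such as anti-HA at 30 min. Settings tried as fixed in advance were values not divided by the library's median, pseudocounts of 0.5 and 0.02, a filter at a mean value of 0.25, the median of bins, the 400 bp upstream of a gene, a model without the course, leaving out each library or sampling point, other distances from the end and an estimated correlation. Settings added after seeing the data were the deposited scores as they stand, log2 bins only, all annotated features, genes of at least 300 bp, library weights, each run alone, the difference of tags within a sampling point, the first 1 kb from the end, and lists without the 2 first-course libraries taken 30 min after release.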

Results

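Sir3 is a subunit of the SIR complex, which silences genes next to telomeres and at the silent mating loci HML and HMR. Its binding was mapped genome-wide by chromatin immunoprecipitation and sequencing (ChIP-seq) as yeast cells left starvation. The tag-switch strain, of S288C descent, carried the RITE cassette at the 3' end of SIR3. In this cassette an estradiol-activated Cre recombinase removes an HA epitope and puts a T7 epitope in its place, so that Sir3 made before the switch carries HA and Sir3 made after it carries T7. Cells starved for 48 h were sampled before the switch, after 16 h of estradiol, and at intervals after release into fresh medium. A second strain, of W303 descent, lacked SIR3 at its own locus and carried Sir3-HA under the GAL1 promoter, which galactose induces and dextrose represses. Of 49 immunoprecipitated libraries, 22 came from the first tag-switch course, 18 from the second and 9 from the overexpression strain. A sampling point had 1 anti-HA and 1 anti-T7 library per course, except for the point of 2 doublings in the first course, which had 2 of each. Library values at a single sampling point therefore had no replicates within a course. Anti-T7 libraries taken before the switch contained no T7 tag and gave the background. Values are multiples of the library's median gene. Depth is unknown, as the tables hold no counts.

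In starved cells, old Sir3 lay at the chromosome ends, over the X elements, the repeats found next to almost every telomere. The cores of these elements had a median of 29.4 times the median gene in the anti-HA library of the first course and 9.05 in the second, against 0.671 and 0.958 in the anti-T7 libraries of the same cells. In a test of all annotated features that was chosen after seeing the data, 12 of 16 X cores were higher with anti-HA than with anti-T7, with a median log2 difference of 4.32. Examples were TEL06R-XC on chromosome 6 (269720 to 270109), higher by 4.70 ± 0.51 (SE, n = 2 and 2, adjusted p = 1.04e-04), and TEL13R-XC on chromosome 13 (923540 to 924019), higher by 4.26 ± 0.46 (SE, adjusted p = 1.04e-04). TEL16R-XC, with a difference of 0.70 ± 0.41 (SE), and TEL07R-XC, with 1.29 ± 0.52 (SE), did not pass. The silencers of HML and HMR, the elements from which silencing of these loci starts, had a mean of 39.2 with anti-HA and 2.19 with anti-T7 in the first course, and 4.76 and 0.630 in the second.

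Among protein-coding genes in starved cells, the largest values lay in genes close to the ends. YCR108C on chromosome 3 (316040 to 316199) had 9.62 ± 2.34 (SD, n = 2) with anti-HA and 0.644 ± 0.548 (SD, n = 2) with anti-T7, a log2 difference of 3.91 ± 0.65 (SE, adjusted p = 0.0931). YFR057W on chromosome 6 (269050 to 269519) had 8.93 ± 4.46 (SD, n = 2) and 2.01 ± 1.30 (SD, n = 2), and YNR077C, annotated over 20 bp on chromosome 14, had 13.0 ± 4.55 (SD, n = 2) and 0.913 ± 0.560 (SD, n = 2). The other genes with the smallest p were CHA1, a serine and threonine deaminase (0.90 ± 0.30, SE), and MPP6, a cofactor of the nuclear exosome (0.67 ± 0.23, SE). With limma 0 of 5585 genes passed, and 16 had an unadjusted p under 0.05. Beside all annotated features YCR108C passed (adjusted p = 0.00600), within a range over its alternatives from 0.00311 to 1.00, the latter without the first-course anti-HA library.

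Of the lists fixed in advance, that of genes within 10 kb of an end rose, with 33 of its 101 members measured. Its median was 0.14 (adjusted p = 7.61e-05, 23 members up and 10 down, and adjusted p = 0.0182 with an estimated correlation). 3 members passed when adjusted over the list alone, against 0 over all genes. Genes of respiration and the tricarboxylic acid cycle were also higher with anti-HA (32 of 37, median 0.21, adjusted p = 6.16e-06, and adjusted p = 0.0224 with an estimated correlation), with CIT1, the mitochondrial citrate synthase, at 0.60 ± 0.56 (SE). Stress and stationary-phase genes were higher (23 of 28, median 0.20, adjusted p = 0.001, and adjusted p = 0.0271 with an estimated correlation), with the small heat shock protein gene HSP42 at 0.54 ± 0.33 (SE). Of the respiration, stress, glycolysis and highly transcribed genes 0 passed singly. All 19 glycolysis and fermentation genes were higher (median 0.26, adjusted p = 4.66e-07, but adjusted p = 0.234 with an estimated correlation). Highly transcribed genes (median 0.27, adjusted p = 3.83e-07, but adjusted p = 0.25 with an estimated correlation) and ribosomal protein genes (median 0.09, adjusted p = 0.0403, but adjusted p = 0.428 with an estimated correlation) were higher. tRNA genes were lower (median -0.35, adjusted p = 7.92e-11, but adjusted p = 0.428 with an estimated correlation), by -0.89 in the first course and with 0.10 in the second.

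**Figure D1:**
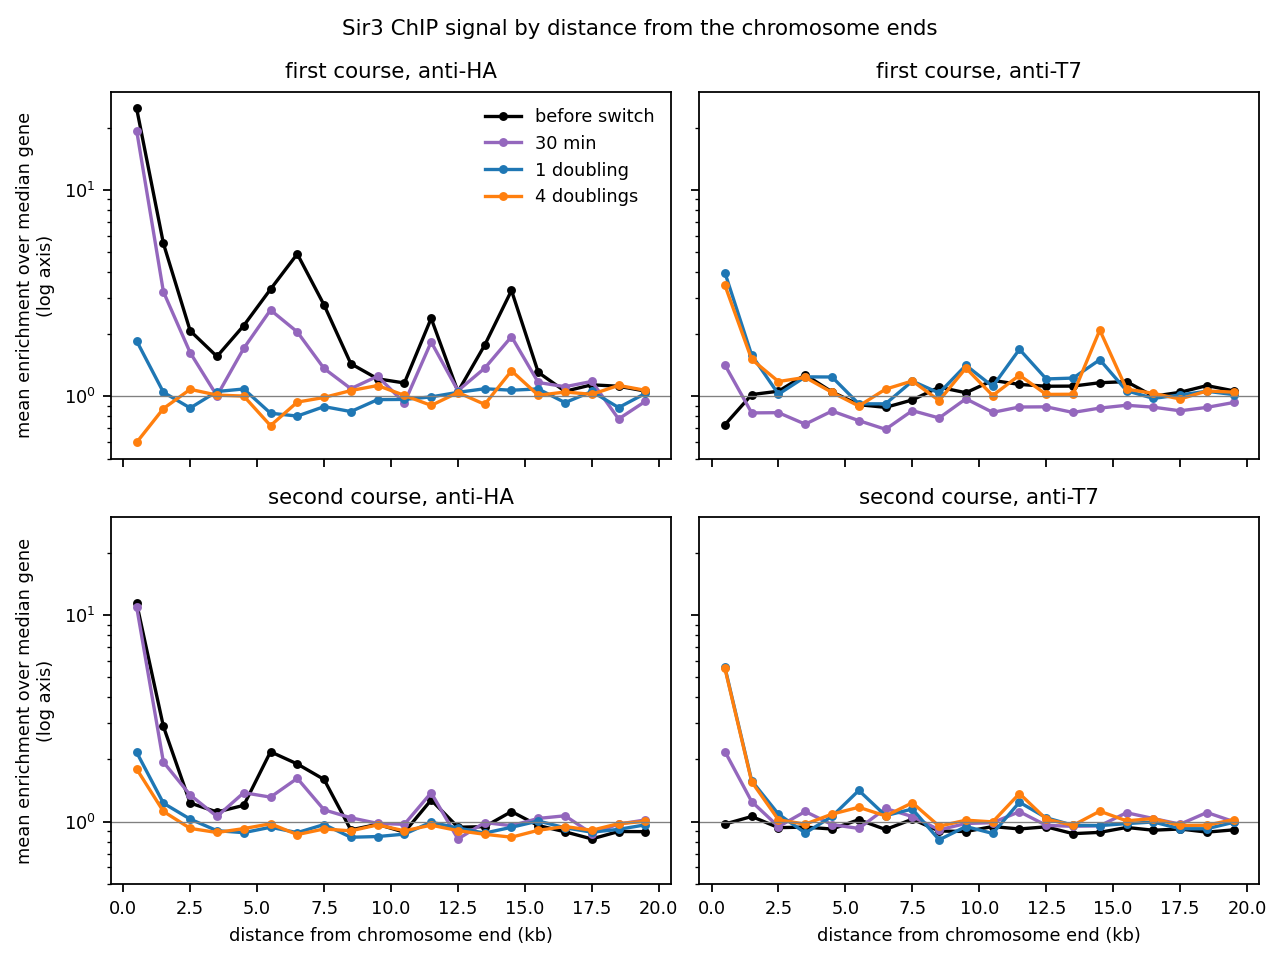
Mean enrichment over the median gene (log axis) in windows of 1 kb by distance from the chromosome ends (kb), for anti-HA and anti-T7 in each tag-switch course, 1 line per sampling point. Before the switch, the first window stood at 24.8 with anti-HA in the first course and at 11.4 in the second course, against 0.729 and 0.973 with anti-T7.

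The next question was how old Sir3 moved after release. At 30 min after release, anti-HA signal over 400 of 5585 genes differed from that in starved cells, 133 higher and 267 lower. All 400 had the same sign in both courses, but with library weights 1 call was left. Bins at exactly 0 made up 53.8% of the first-course and 10.6% of the second-course anti-HA library at 30 min. Among the largest rises were CCW12, a cell wall mannoprotein on chromosome 12 (369700 to 370109), with 4.36 ± 0.138 (SD, n = 2) against 1.04 ± 0.698 (SD, n = 2), and RPS14B, a protein of the small ribosomal subunit on chromosome 10 (73790 to 74619), with 3.22 ± 0.367 against 0.961 ± 0.0398 (SD, n = 2 each). Their log2 changes were 2.12 ± 0.60 (SE, adjusted p = 0.0434) and 1.64 ± 0.30 (SE, adjusted p = 0.00511). The other large rises were YCR050C (2.26 ± 0.45, SE), COA3, an assembly factor of cytochrome oxidase (1.78 ± 0.42, SE), YOR072W (1.78 ± 0.41, SE), cytochrome b5 CYB5 (1.74 ± 0.33, SE), SDH5, which serves succinate dehydrogenase (1.73 ± 0.36, SE), and EMP24, a protein of transport vesicles (1.63 ± 0.32, SE). Among the largest falls, TIM8, a chaperone of mitochondrial import on chromosome 10 (676970 to 677239), was listed at 0 in both libraries at 30 min (adjusted p = 1.76e-06), as were YBR072C-A (adjusted p = 0.00340), YGL041C-B and YFL019C (adjusted p = 0.00182 each). COX26, a subunit of cytochrome oxidase on chromosome 4 (691020 to 691229), had 0.0726 ± 0.103 (SD, n = 2) against 1.44 ± 0.139 (SD, n = 2), a log2 change of -3.29 ± 0.50 (SE, adjusted p = 0.00182). The remaining large falls were YAR035C-A (-3.31 ± 0.67, SE), YMR007W (-3.06 ± 0.33, SE) and YDL022C-A (-2.92 ± 0.44, SE).

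By list, ribosomal protein genes rose at 30 min (89 of 116 up, median 0.40, adjusted p = 1.37e-07, but adjusted p = 0.113 with an estimated correlation). Over all genes 14 of them rose and 2 fell, and 26 and 2 when adjusted over the list alone, such as RPP0 (1.5 ± 0.28, SE, adjusted p = 0.00696) and RPS28A (-2.02 ± 0.43, SE, adjusted p = 0.0118). Highly transcribed genes rose (median 0.54, adjusted p = 9.32e-05, but adjusted p = 0.356 with an estimated correlation), 6 of 21 singly and 7 when adjusted over the list alone. Glycolysis and fermentation genes rose (median 0.38, adjusted p = 0.0403, but adjusted p = 0.563 with an estimated correlation), with 5 of 19 passing upward over all genes, and 6 up and 1 down over the list alone. Alcohol dehydrogenase ADH1 rose by 1.48 ± 0.27 (SE, adjusted p = 0.00592) and the aldolase FBA1 by 1.30 ± 0.28 (SE, adjusted p = 0.0118). Hexose transport genes rose (6 of 8 up, median 0.45, adjusted p = 0.0248, but adjusted p = 0.234 with an estimated correlation), and the transporters HXT1 (1.01 ± 0.19, SE, adjusted p = 0.00722) and HXT8 (0.77 ± 0.22, SE, adjusted p = 0.0448) passed, also when adjusted over the list alone. Respiration genes fell (26 of 37 down, median -0.43, adjusted p = 0.0403, but adjusted p = 0.234 with an estimated correlation), 1 rising and 4 falling singly, and 1 and 6 when adjusted over the list alone. CIT1 changed by -2.76 ± 0.56 (SE, adjusted p = 0.0102) and QCR10 of the cytochrome bc1 complex by -2.26 ± 0.43 (SE, adjusted p = 0.00722).

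Stress genes did not shift as a list at 30 min (median -0.16, adjusted p = 0.603), although 3 of 28 fell, also when adjusted over the list alone: HSP26 (-2.50 ± 0.58, SE, adjusted p = 0.0180), HSP42 (-2.19 ± 0.33, SE, adjusted p = 0.00182) and the nicotinamidase PNC1 (-2.11 ± 0.60, SE, adjusted p = 0.0448). The lists of ribosome biogenesis (median 0.09, adjusted p = 0.213), mating (0.21, adjusted p = 0.256), cell cycle entry (0.07, adjusted p = 0.367), histone (0.22, adjusted p = 0.512), SIR (-0.12, adjusted p = 0.603), galactose (-0.28, adjusted p = 0.664) and tRNA genes (-0.48, adjusted p = 0.882) did not pass. Single members passed among them, such as NSR1 (-1.61 ± 0.30, SE, adjusted p = 0.00633) and RPA135 (0.91 ± 0.23, SE, adjusted p = 0.0282) of ribosome biogenesis, the helicase subunit MCM3 (1.01 ± 0.19, SE, adjusted p = 0.00722), the kinase FUS3 of the mating pathway (1.01 ± 0.29, SE, adjusted p = 0.0448) and 3 tRNA genes upward and 7 downward. The multicopy subtelomeric families PAU (4 measured, median -1.37, adjusted p = 0.463), COS (5 measured, -0.21, adjusted p = 0.704) and flocculin (3 measured, -0.27, adjusted p = 0.618) passed neither here nor in any other comparison, and nor did cell cycle entry. Genes 0 to 10 kb (median -0.37, adjusted p = 0.299), 10 to 20 kb (0.01, adjusted p = 0.504) and 20 to 30 kb from an end (-0.03, adjusted p = 0.465) did not shift as lists. Single genes of these lists passed in both directions. Among those that fell were IRC7 (-2.74 ± 0.42, SE, adjusted p = 0.00182) and YFR057W (-1.90 ± 0.52, SE, adjusted p = 0.0381, from 0.00419 to 0.623 over its alternatives). Signal at the X cores stood at 15 and 4.82 in the first and second course, and 1 of 16, TEL07R-XC, passed (-1.80 ± 0.52, SE, adjusted p = 0.0493), against 0 to 3 under other settings.

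Of the bins of the first-course anti-HA library at 30 min, 53.8% held exactly 0, and 10.6% of those in the second course. Genes called lower had a median annotated length of 770 bp and genes called higher 950 bp, against 1190 bp for all genes. Weighting libraries by their spread left 1 call (414 genes at unadjusted p under 0.05), and the deposited scores as they stand left 0 with limma (561 genes at unadjusted p under 0.05). Without division by the library median the split was 37 higher and 352 lower, with the median of bins 183 and 1586, and single libraries moved the total from 14, without the first-course library before the switch, to 1707, without the second-course library at 30 min.

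After the first doubling, old Sir3 had left most X cores. Among all annotated features, 10 of 16 X cores were lower than in starved cells, with a median log2 change of -3.17 over the 16. TEL06R-XC changed by -3.71 ± 0.51 (SE, n = 2 and 2, adjusted p = 0.00446) and TEL13R-XC by -3.21 ± 0.46 (SE, adjusted p = 0.00446). X core medians stood at 1.48 and 1.75 in the first and second course. Among protein-coding genes limma called 0 of 5585, with 219 at an unadjusted p under 0.05. YFR057W had 1.49 ± 0.344 (SD, n = 2) against 8.93 ± 4.46 (SD, n = 2), a log2 change of -2.43 ± 0.52 (SE, adjusted p = 0.498), with adjusted p from 0.0223 to 1.00 over its alternatives. RPS22B of the small ribosomal subunit (1.19 ± 0.24, SE), INA1 (1.31 ± 0.28, SE), LSM7 of an RNA-binding ring complex (-0.99, adjusted p = 0.999) and RPL37A (0.89, adjusted p = 0.999) followed.

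As lists at 1 doubling, ribosomal protein genes rose (102 of 116 up, median 0.39, adjusted p = 2.01e-19, and adjusted p = 0.0140 with an estimated correlation), with 1 passing when adjusted over the list alone and 0 over all genes. Genes within 10 kb of an end fell (24 of 33 down, median -0.21, adjusted p = 0.00383, but adjusted p = 0.0564 with an estimated correlation), 1 of them when adjusted over the list alone. Respiration genes fell (median -0.32, adjusted p = 0.0187, but adjusted p = 0.203 with an estimated correlation), with the malate dehydrogenase MDH1 at -0.97 ± 0.32 (SE) and the oxidase subunit COX8 at 0.84 ± 0.49 (SE). tRNA genes rose (median 0.81, adjusted p = 5.04e-16, but adjusted p = 0.356 with an estimated correlation), as did highly transcribed genes (median 0.20, adjusted p = 0.0248, but adjusted p = 0.561 with an estimated correlation), the latter with -0.04 in the first course and 0.43 in the second. Hexose transport genes rose (median 0.10, adjusted p = 0.0297, but adjusted p = 0.234 with an estimated correlation), 2 when adjusted over the list alone, with HXT3 at 1.02 ± 0.27 (SE). Mating genes rose (12 of 16 up, median 0.29, adjusted p = 0.0437, but adjusted p = 0.2 with an estimated correlation), with the pheromone receptor STE2 at 0.78 ± 0.26 (SE). Ribosome biogenesis genes rose (26 of 44 up, median 0.04, adjusted p = 0.0212, but adjusted p = 0.192 with an estimated correlation), with YTM1 at 1.03 ± 0.33 (SE).

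At 4 doublings the first 1 kb from the ends stood at 0.599 with anti-HA in the first course and 1.80 in the second, against 0.729 and 0.973 with anti-T7 before the switch. Among all annotated features, 44 were lower than in starved cells and 0 higher, including 12 of 16 X cores (median -3.94). TEL08R-XC on chromosome 8 (556110 to 556589) changed by -5.34 ± 0.76 (SE, n = 2 and 2, adjusted p = 0.00153) and TEL06R-XC by -4.73 ± 0.51 (SE, adjusted p = 1.91e-04). Of the genes close to the ends, YFR057W stood at 0.866 ± 0.0966 (SD, n = 2) against 8.93 ± 4.46 (SD, n = 2). YCR108C stood at 0.819 ± 0.820 (SD, n = 2) against 9.62 ± 2.34 (SD, n = 2). Their log2 differences were -3.13 ± 0.52 and -3.75 ± 0.65 (SE, adjusted p = 0.0766 each), and YNR077C had -3.79 ± 0.89 (SE). With limma 0 of 5585 genes passed, and 156 had an unadjusted p under 0.05. Beside all annotated features both passed, YFR057W with adjusted p = 0.00561 and YCR108C with adjusted p = 0.00880. Over their alternatives the adjusted p ranged from 9.56e-04 to 1.00 for YFR057W and from 0.00649 to 1.00 for YCR108C, the upper ends without the first-course library at 4 doublings.

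Ribosomal protein genes rose as a list at 4 doublings (105 of 116 up, median 0.42, adjusted p = 8.29e-24, and adjusted p = 0.0140 with an estimated correlation), with 0 passing singly, such as RPS14B (0.97) and RPL37A (0.94 ± 0.23, SE). The anti-T7 library of log-phase cells, which carry no T7 tag, stood 0.26 above that of starved cells over the same genes. In this library 36.4% of bins held exactly 0. Genes within 10 kb of an end fell (21 of 33 down, median -0.09, mean -0.51, adjusted p = 1.72e-04, and adjusted p = 0.0218 with an estimated correlation), 3 when adjusted over the list alone. tRNA genes rose (146 of 164 up, median 1.11, adjusted p = 8.35e-26, but adjusted p = 0.239 with an estimated correlation). Rises that were lost with an estimated correlation were those of highly transcribed genes (median 0.32, adjusted p = 7.88e-06, but adjusted p = 0.302 with an estimated correlation), histone genes (8 of 9 up, median 0.35, adjusted p = 0.0173, but adjusted p = 0.356 with an estimated correlation), mating genes (median 0.24, adjusted p = 0.0139, but adjusted p = 0.106 with an estimated correlation) and glycolysis genes (median 0.17, adjusted p = 0.0403, but adjusted p = 0.563 with an estimated correlation). Among histone genes, HHO1 of linker histone had 0.71 ± 0.66 (SE), HHT1 of histone H3 0.49 ± 0.36 (SE) and HTZ1 of the variant H2A.Z -0.11 ± 0.45 (SE). Stress genes fell (21 of 28 down, median -0.22, adjusted p = 0.0281, but adjusted p = 0.128 with an estimated correlation), with HSP30 and YGP1 at -0.74 each. The comparisons at 30 min, 1 and 4 doublings share the libraries taken before the switch, so their lists are not independent of each other.

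Over each course, the median of genes within 10 kb of an end was set against the number of doublings in a family of 4 relations. For anti-HA this median lay near the median gene, from 0.912 to 1.36 in the first course and from 0.849 to 1.14 in the second. Libraries sampled before any doubling all counted as without doublings. The permutations treat the libraries of a course as exchangeable, which serial samples need not be, so the p-values may overstate the evidence. For anti-HA in the second course, r was -0.853 (n = 8, exact permutation p = 0.00134, adjusted p = 0.00536) and rho -0.952 (exact permutation p = 0.00149, adjusted p = 0.00595). Without the 2 libraries farthest from the median number of doublings, r was -0.805 (n = 6, exact permutation p = 0.075, adjusted p = 0.15) and rho -0.880 (exact permutation p = 0.05, adjusted p = 0.1). Both values lay close to those over all 8 libraries. For genes within 20 kb r was -0.526 (permutation adjusted p = 0.363). With the mean over genes it was -0.490 (0.170), and for the first 1 kb -0.494 (0.126). In these 3 settings rho was -0.488, -0.903 and -0.903. The call of r held for 5 kb (-0.760) and without division by the median (-0.823). For anti-HA in the first course, r was -0.648 (n = 11, permutation p = 0.0284, adjusted p = 0.0568) and rho -0.784 (permutation p = 0.00700, adjusted p = 0.0140), and r was -0.735 without the 2 farthest libraries. There rho was -0.229 without division by the median (permutation adjusted p = 0.818) and -0.736 for 20 kb (0.0554), and passed under the other settings. For anti-T7, r was 0.327 in the first course (n = 10, permutation p = 0.363, adjusted p = 0.484) with rho 0.583 (permutation p = 0.0819, adjusted p = 0.109). In the second, r was -0.0173 (n = 7, exact permutation p = 0.975, adjusted p = 0.975) with rho 0.108 (exact permutation p = 0.822, adjusted p = 0.822). Without the 2 farthest libraries, r was 0.534 in the first course (n = 8, exact permutation p = 0.173, adjusted p = 0.173). In the second it was 0.777 (n = 5, exact permutation p = 0.133, adjusted p = 0.173).

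**Figure D2:**
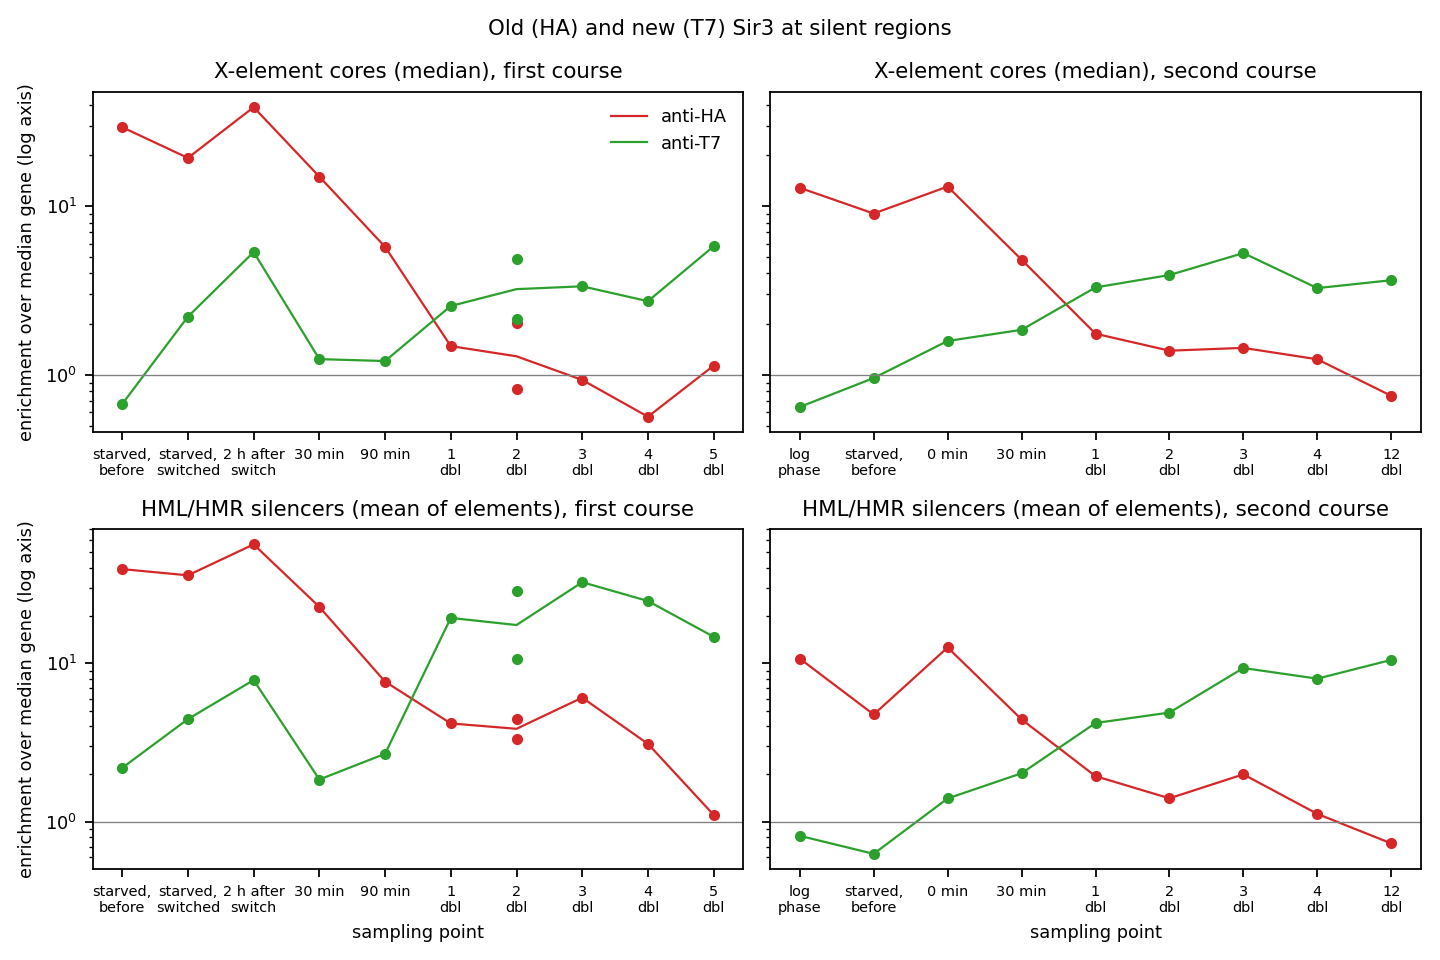
Enrichment over the median gene (log axis) at X-element cores (median of cores) and at the silencers of HML and HMR (mean of silencers) by sampling point, 1 point per library, with anti-HA in red and anti-T7 in green and a line through the geometric mean of the libraries of a point. Anti-HA at the silencers went from 39.2 before the switch to 3.11 at 4 doublings in the first course, and anti-T7 from 2.19 to 24.7, with 4 silencers measured before the switch and 3 at 4 doublings.

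New Sir3 was followed with anti-T7 against the same antibody before the switch. At 30 min after release, 0 of 16 X cores passed (median log2 difference 0.72), and the silencers stood at 1.85 in the first course and 2.03 in the second, against 2.19 and 0.630 before the switch. Over protein-coding genes limma called 0 of 5585, with 326 at an unadjusted p under 0.05. The genes with the smallest p were TIM8 (0.482 ± 0.193 against 1.54 ± 0.355, SD, n = 2 each, log2 difference -1.52 ± 0.26, SE, adjusted p = 0.144), the fatty acid activating enzyme FAA2 (-0.90 ± 0.19, SE), VPH2 of proton pump assembly (-1.68), the Mediator subunit MED7 (1.18) and the cyclin PHO80 (-0.94), the last 4 with adjusted p = 0.586 each. As lists, tRNA genes rose (median 1.16, adjusted p = 1.78e-21, but adjusted p = 0.285 with an estimated correlation), with 2.22 in the first course and 0.06 in the second. Ribosomal protein genes rose (85 of 116 up, median 0.21, adjusted p = 1.38e-05, but adjusted p = 0.2 with an estimated correlation), as did glycolysis genes (15 of 19 up, median 0.21, adjusted p = 4.52e-04, but adjusted p = 0.365 with an estimated correlation), 3 of them when adjusted over the list alone. The glycolysis medians had opposite signs in the first and second course, 0.55 and -0.08. Highly transcribed genes rose (median 0.23, adjusted p = 7.26e-04, but adjusted p = 0.405 with an estimated correlation). In the first-course anti-T7 library at 30 min, 54.2% of bins were linear and not divided by input, and without the 2 libraries of that point highly transcribed genes lost their call and their sign (adjusted p = 0.950).

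After 1 doubling, new Sir3 was found at chromosome ends, where some anti-T7 signal had stood before release. In the first course the first 1 kb stood at 5.79 at 2 h after the switch, 1.42 at 30 min after release and 3.97 at 1 doubling. In the second it stood at 2.54 at release, 2.19 at 30 min and 5.58 at 1 doubling. Among all annotated features 12 were higher than before the switch, among them 3 X cores. TEL01R-XC on chromosome 1 (229410 to 229879) rose by 3.71 ± 0.51 (SE, n = 2 and 2, adjusted p = 0.00597), TEL11L-XC on chromosome 11 (460 to 819) by 3.16 ± 0.60 (SE, adjusted p = 0.0439) and TEL04R-XC on chromosome 4 by 2.50 ± 0.46 (SE, adjusted p = 0.0439). The median over the 16 X cores was 1.51. The silencers reached 19.3 in the first course (3 of 4 measured) and 4.20 in the second. With limma 0 of 5585 genes passed, and 235 had an unadjusted p under 0.05. YCR108C had 4.90 ± 1.40 (SD, n = 2) against 0.644 ± 0.548 (SD, n = 2), a difference of 2.95 ± 0.65 (SE, adjusted p = 0.920), and RPL40B of the large ribosomal subunit 1.28 ± 0.28 (SE, adjusted p = 0.920). YKR041W (-1.35, 131 bp from a tRNA gene), CBS1, which activates translation of cytochrome b (-1.09), and YPR195C (-1.66) completed the smallest p-values.

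At 4 doublings 4 features were higher than before the switch, among them TEL01R-XC (3.14 ± 0.51, SE, adjusted p = 0.0459) and TEL11L-XC (3.53 ± 0.60, SE, adjusted p = 0.0480). The X core median was 2.01. With run 1 alone of the first-course libraries before the switch 0 X cores passed at 1 and at 4 doublings, and with run 2 alone 5 did at each. The silencers stood at 24.7 (3 of 4 measured) and 8.0. With limma 0 of 5585 genes passed, and 49 had an unadjusted p under 0.05. RPC17, a subunit of RNA polymerase III whose gene lies 191 bp from a tRNA gene, had a difference of 2.31 ± 0.53 (SE, adjusted p = 1.00), 3.82 in the first course and 0.79 in the second. YCR108C had 2.41 ± 0.65 (SE), YNR077C 2.64 ± 0.89 (SE), YOR034C-A 0.87 and YPL062W -1.45. Against 30 min after release, 0 of 5585 genes passed at 4 doublings with limma (152 at an unadjusted p under 0.05). The smallest p were those of MRPS28 of the mitochondrial ribosome (1.08), the Mediator subunit SRB5 (0.72), LCL3 (1.12), FZF1, a regulator of sulfite transport (-0.97), and FAA2 (0.66).

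Ribosomal protein genes rose in anti-T7 at 1 doubling (93 of 116 up, median 0.29, adjusted p = 6.32e-11, and adjusted p = 0.0443 with an estimated correlation), 1 when adjusted over the list alone. They also rose at 4 doublings (101 of 116 up, median 0.29, adjusted p = 3.82e-17, and adjusted p = 0.0182 with an estimated correlation), with RPL32 at 0.81 ± 0.31 (SE). Highly transcribed genes rose at 1 doubling (median 0.22, adjusted p = 0.0170, but adjusted p = 0.545 with an estimated correlation), with -0.12 in the first course and 0.58 in the second. They rose at 4 doublings (median 0.21, adjusted p = 7.36e-04, but adjusted p = 0.405 with an estimated correlation). Glycolysis genes rose at 4 doublings (median 0.13, adjusted p = 0.0234, but adjusted p = 0.545 with an estimated correlation). They fell between 30 min and 4 doublings (median -0.16, adjusted p = 0.0248, but adjusted p = 0.547 with an estimated correlation), with -0.40 in the first course and 0.05 in the second. This call was lost without the 2 first-course libraries at 30 min (adjusted p = 0.695). SIR genes rose between 30 min and 4 doublings (7 of 7 up, median 0.14, adjusted p = 0.0437, but adjusted p = 0.203 with an estimated correlation), with SIR4 at 0.52 ± 0.25 (SE) and SIR3 at 0.37 ± 0.26 (SE). Genes within 10 kb of an end did not pass as a list in any anti-T7 comparison. Over all comparisons, 55 of 188 list tests passed, 48 upward and 7 downward, and 10 did so with an estimated correlation. Median, mean and test differed in sign in 18 tests, of which 0 passed.

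**Figure D3:**
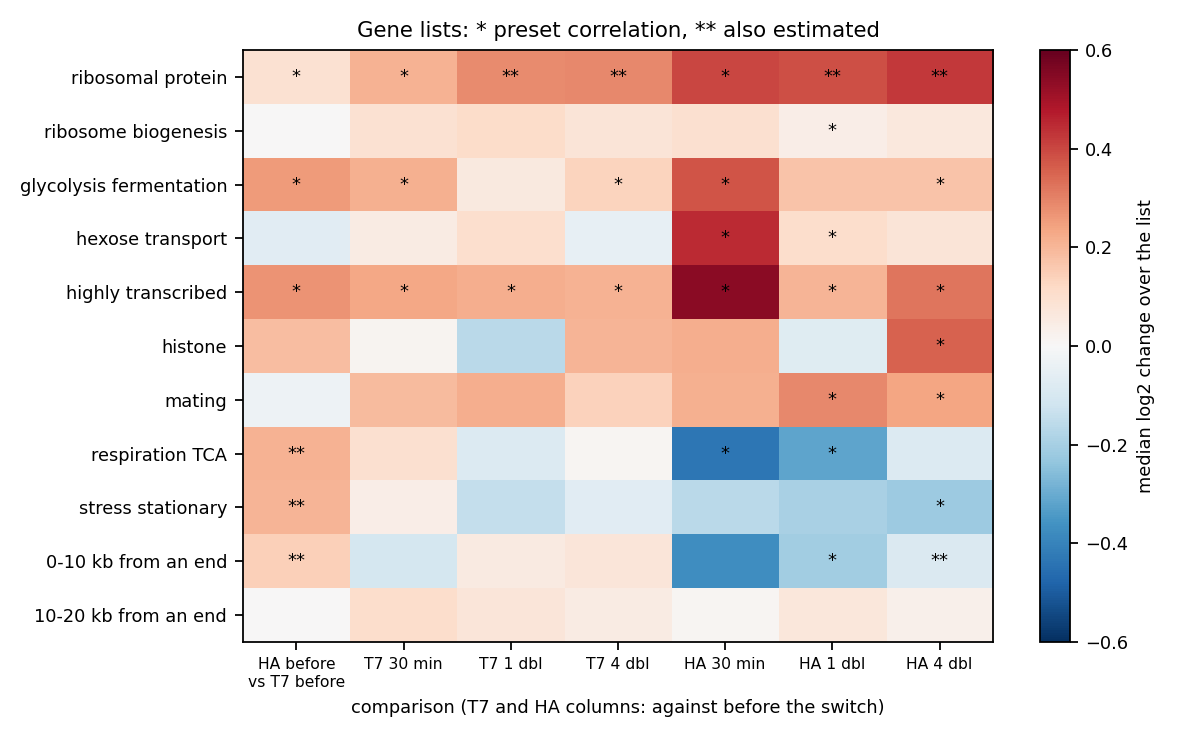
Median log2 change over the members of each list (colour scale) in each tag-switch comparison, with 1 star for an adjusted p under 0.05 at the preset correlation and a pair of stars where it held with an estimated correlation. Ribosomal protein genes held in anti-HA and anti-T7 at 1 and 4 doublings, with medians of 0.39, 0.42, 0.29 and 0.29.

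tRNA genes gained anti-T7 signal, far more in the first course than in the second. At 1 doubling 157 of 164 measured tRNA genes were higher than before the switch (median log2 2.35, adjusted p = 3.67e-81, and adjusted p = 0.0362 with an estimated correlation), 97 when adjusted over the list alone. At 4 doublings 160 of 164 were higher (median 2.39, adjusted p = 1.56e-144, and adjusted p = 0.0140 with an estimated correlation), 115 when adjusted over the list alone. The median at 4 doublings was 3.77 in the first course and 0.92 in the second. Against 30 min after release the list rose by 1.12 (adjusted p = 5.05e-27, but adjusted p = 0.234 with an estimated correlation). Among all annotated features, 7 tRNA genes passed at 1 doubling and 1 at 4 doublings, tH(GUG)G1 at both (3.38, adjusted p = 0.0404, and 3.25). tT(AGU)C on chromosome 3 (295490 to 295569) had 13.8 ± 10.5 (SD, n = 2) at 1 doubling against 0.728 ± 0.273 (SD, n = 2). In the first course the median tRNA gene stood at 1.59 before the switch, 8.68 at 30 min, 27.1 at 1 doubling and 28.8 at 4 doublings with anti-T7, and at 0.741, 1.34 and 1.97 before the switch, at 1 and at 4 doublings with anti-HA. In the second course anti-T7 gave 0.763, 1.62 and 1.62 at these points, and 1.31 in log-phase cells that carry no T7 tag.

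**Figure D4:**
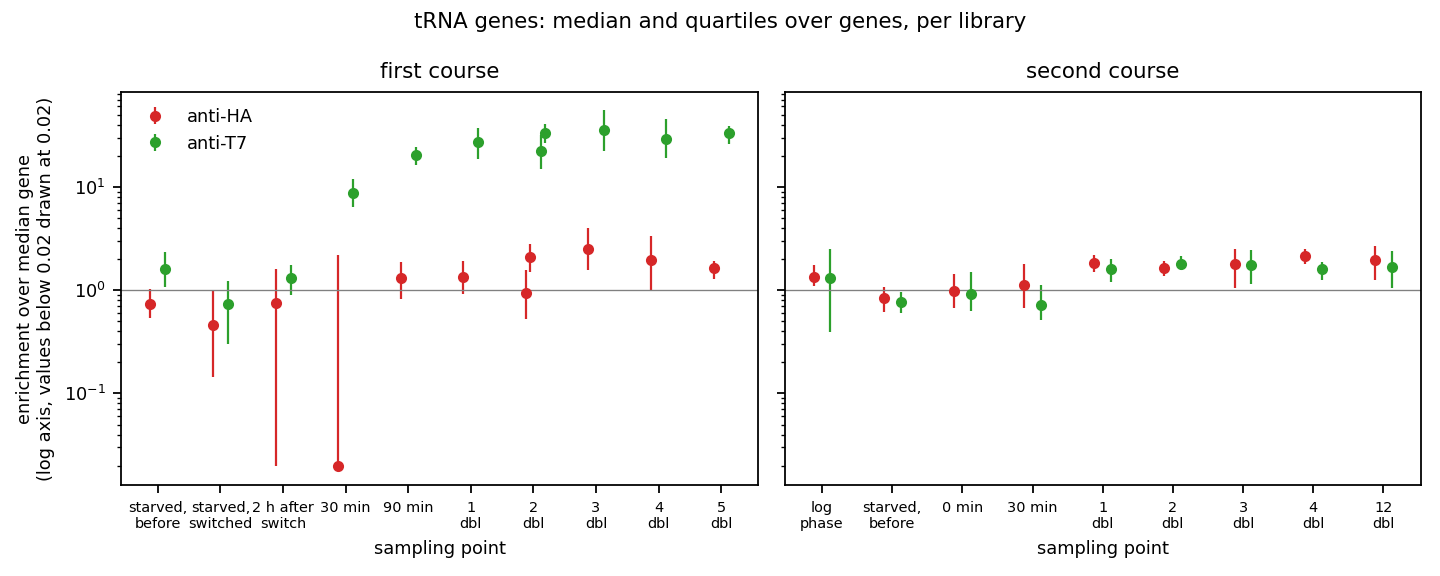
Median tRNA gene of each library with the quartiles over tRNA genes as bars, as enrichment over the median gene (log axis, values under 0.02 drawn at 0.02), by sampling point, with anti-HA in red and anti-T7 in green. In the first course anti-T7 ran from 8.68 at 30 min to 35.9 at 3 doublings, and in the second course it was 1.81 at 2 doublings.

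In the strain that overexpresses Sir3, galactose was compared with dextrose after release to ask how far Sir3 reaches when it is induced. As this strain lacks SIR3 at its own locus, dextrose gives repressed Sir3 and not its normal level, and the sugar differs as well. The comparison therefore does not measure spread beyond that at a normal level of Sir3. Sir3-HA covered the chromosome ends far inward in galactose. The mean over ends stood at 20.7, 8.70 and 1.09 at 10, 20 and 30 kb from the end after 12 doublings in galactose. The stretch of consecutive windows at 2 or more times the median gene, a measure chosen after seeing the data, had a median over 32 arms of 1.5 kb in starved cells, 8.5 kb after 1 h, 13 kb after 2 doublings and 18.5 kb after 12 doublings in galactose (quartiles 10.75 and 21.5 kb). In dextrose the median was 0 kb at each point, with 15, 2 and 0 arms having any such window at 1 h, 2 and 12 doublings. X cores stood at 19.2, 23.6 and 37.8 in galactose and at 5.21, 0.913 and 0.752 in dextrose at these points. The silencers stood at 18.5, 19.5 and 42.8 in galactose and at 8.36, 2.0 and 0.503 in dextrose. In log-phase cells of the tag-switch strain, with SIR3 at its own locus, the median reach with anti-HA was 2 kb. With anti-T7 in these cells, which carry no T7 tag, it was 0 kb, although 5 arms had some reach, up to 21 kb. In both log-phase libraries 36.4% of bins were linear and not divided by input. Windows without a value were passed over, so the reach of single arms can be overstated.

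With galactose 3 of 5654 genes were higher than with dextrose and 0 lower (719 at an unadjusted p under 0.05), all within 10 kb of an end. AAD15, a putative aryl-alcohol dehydrogenase on chromosome 15 (1650 to 2089), had 32.7 ± 27.9 (SD, n = 3) against 1.01 ± 0.614 (SD, n = 3), a log2 difference of 4.70 ± 0.25 (SE, adjusted p = 6.83e-04). COS10 on chromosome 14 (779920 to 781049), of a subtelomeric family with near-identical copies, had 19.6 ± 17.4 (SD, n = 3) against 0.719 ± 0.474 (SD, n = 3), a difference of 4.41 ± 0.25 (SE, adjusted p = 6.83e-04). YHL048C-A on chromosome 8 (5670 to 5809) had 26.7 ± 24.9 (SD, n = 3) against 1.02 ± 0.933 (SD, n = 3), a difference of 4.53 ± 0.48 (SE, adjusted p = 0.0387). YER188C-A (4.87, adjusted p = 0.0890) and YAL067W-A (4.73, adjusted p = 0.106) did not pass. Without the libraries at 2 doublings 0 genes passed (410 at an unadjusted p under 0.05) and without those at 1 h 33 did. The 400 bp upstream of genes gave 39 calls that shared 0 genes with these. YHL048C-A was also lost with a pseudocount of 0.02 (adjusted p = 0.0563), without 12 doublings (adjusted p = 0.0541) and beside all annotated features (adjusted p = 0.0822). Among those features 0 of 14 X cores passed, with a median of 3.91. The model takes the same sugar difference at all points. Differences that grew with time, as at the X cores, enter the spread it leaves over and make a call less likely. The lack of a call there is therefore not evidence of no difference. The SDs of these genes are over the 3 sampling points and not over replicates.

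Of 101 genes within 10 kb of an end, 28 were measured in this model. They rose as a list in galactose (26 up, median 3.21, adjusted p = 9.07e-22, but adjusted p = 0.284 with an estimated correlation). Over all genes 3 of the 28 passed, and 20 when adjusted over the list alone. The median difference of the list was 1.14 at 1 h, 2.97 at 2 doublings and 4.98 at 12 doublings. Genes 10 to 20 kb from an end rose (66 of 79 up, median 0.60, adjusted p = 2.68e-10, but adjusted p = 0.418 with an estimated correlation), 10 when adjusted over the list alone, such as YOL162W (3.49 ± 0.60, SE), with medians of 0.09, 0.52 and 1.43 at the 3 points. Genes 20 to 30 kb from an end rose (82 of 120 up, median 0.17, adjusted p = 0.0129, but adjusted p = 0.538 with an estimated correlation), with -0.01, 0.18 and 0.28 at the 3 points. Galactose genes rose (6 of 7 up, median 1.13, adjusted p = 2.82e-05, but adjusted p = 0.204 with an estimated correlation), 5 when adjusted over the list alone and 0 over all genes. The transporter GAL2 had 1.65 ± 0.30 (SE), the galactokinase GAL1 1.48 ± 0.25, GAL10 1.33 ± 0.23, the transferase GAL7 1.13 ± 0.29, the inducer GAL3 0.67, the repressor GAL80 0.35 and the activator GAL4 -0.01. SIR genes did not pass as a list (median -0.14, adjusted p = 0.644), with SIR3 itself at 0.95 ± 0.32 (SE, adjusted p = 0.307).

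Highly transcribed genes rose in galactose (20 of 21 up, median 0.69, adjusted p = 4.91e-11, but adjusted p = 0.102 with an estimated correlation), 11 when adjusted over the list alone. Glycolysis genes rose (18 of 19 up, median 0.67, adjusted p = 5.35e-08, but adjusted p = 0.204 with an estimated correlation), 10 when adjusted over the list alone, with the glucokinase GLK1 at 1.35 ± 0.31 (SE). tRNA genes rose (219 of 257 up, median 0.87, adjusted p = 2.37e-16, but adjusted p = 0.356 with an estimated correlation), with 27 up and 1 down when adjusted over the list alone. Ribosomal protein genes rose (106 of 123 up, median 0.38, adjusted p = 7.04e-10, but adjusted p = 0.365 with an estimated correlation), 2 when adjusted over the list alone, such as RPL5 (1.16). Histone genes rose (10 of 10 up, median 0.43, adjusted p = 0.0135, but adjusted p = 0.25 with an estimated correlation), with HHF1 of histone H4 at 0.85 ± 0.47 (SE). Respiration genes rose (median 0.25, adjusted p = 0.0377, but adjusted p = 0.379 with an estimated correlation). COS genes did not pass (4 measured, median 1.33, adjusted p = 0.137, 1 over all genes and 2 up and 1 down when adjusted over the list alone), with COS8 at 2.62 ± 0.70 (SE).

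Raffinose, which neither induces the GAL1 promoter nor strongly represses it, gave 0 of 5654 genes against dextrose with limma (220 at an unadjusted p under 0.05). The smallest p were those of DAL82, a regulator of nitrogen use (1.29 ± 0.26, SE), MRX20 (-1.15), RSO55 (1.16), the vacuolar iron transporter FTH1 (-1.39) and the 14-3-3 protein BMH1 (1.22). Each had an adjusted p of 0.995. Genes within 10 kb of an end did not pass (median 0.09, adjusted p = 0.965), and X cores stood at 0.894 at 2 doublings and 1.88 at 12 doublings. At 12 doublings 12 of 32 arms had windows at 2 or more times the median gene, reaching up to 21 kb, against 0 arms in dextrose. The untagged anti-T7 library of log-phase cells had 5 such arms, also up to 21 kb, so the reach of a single arm is not evidence of Sir3. Highly transcribed genes rose (median 0.29, adjusted p = 7.88e-06, but adjusted p = 0.192 with an estimated correlation), as did ribosomal protein genes (median 0.11, adjusted p = 0.0248, but adjusted p = 0.693 with an estimated correlation) and tRNA genes (median 0.19, adjusted p = 0.0282, but adjusted p = 0.747 with an estimated correlation). The last 2 changed sign between 2 and 12 doublings, the only points with raffinose, from 0.13 to -0.05 and from 0.43 to -0.12.

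**Figure D5:**
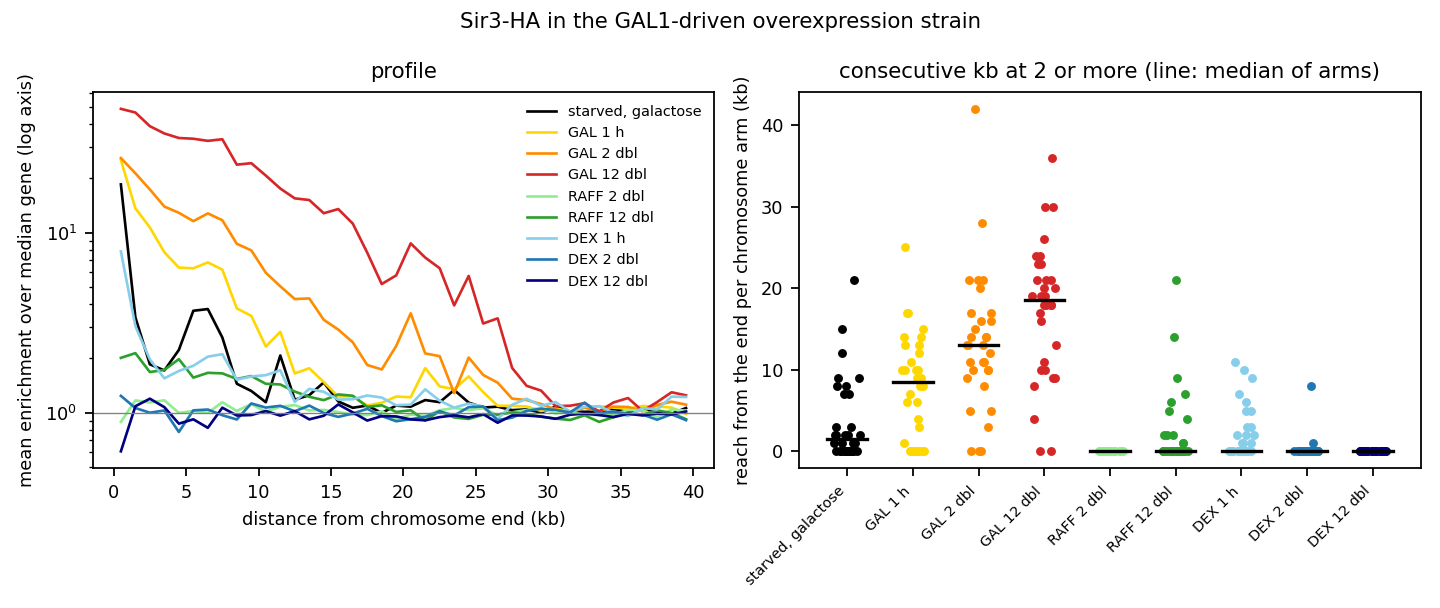
Mean Sir3-HA enrichment over the median gene (log axis) by distance from the chromosome ends (kb) in each library of the overexpression strain, and the reach from the end in kb for each of 32 chromosome arms (points) with the median of arms (black line). The median reach was 18.5 kb after 12 doublings in galactose and 0 kb in each dextrose and raffinose library, although 12 arms had some reach after 12 doublings in raffinose.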

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

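Of the tests in this part, those of X cores among all annotated features, of a shared input, of another protein in place of Sir3-T7 and of unequal library noise were chosen after seeing the results. The difference between anti-T7 and anti-HA at tRNA genes after release was larger in the first course than in the second by 4.34 log2 units (4.17 ± 0.56, SD, n = 6 pairs of libraries, against -0.17 ± 0.26, SD, n = 5 pairs, exact permutation p = 0.00216, adjusted p = 0.0173), a difference between groups. The difference that stood before the switch was not taken out. At that point anti-T7 lay above anti-HA at tRNA genes in the first course but not in the second. At 4 doublings the gain of anti-T7 minus that of anti-HA had a median of 2.75 in the first course and -0.25 in the second. The pairs of a course, 2 of them at 2 doublings in the first course, come from 1 culture series and are not fully independent. The p-value measures the spread between sampling points. It does not measure that between courses, as only 1 course stands on each side. Without the 30 min points the difference was 4.06 (exact permutation p = 0.00794, adjusted p = 0.0635), where 126 splits allow no smaller p, so that this test could not pass alone over 8 tests.

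The 2 tags also differed in how they changed after release, by a test of the difference itself. For genes within 10 kb of an end, the anti-HA change minus the anti-T7 change had a median of -0.246 at 1 doubling (adjusted p = 2.92e-06, and adjusted p = 0.00411 with an estimated correlation) and of -0.146 at 4 doublings (adjusted p = 1.18e-05, and adjusted p = 0.00411 with an estimated correlation). At 30 min the median was -0.281 and did not pass (adjusted p = 0.871), and 0 of 16 X cores passed. Among single genes, 4 had a lower anti-HA than anti-T7 change at 30 min, with MPP6 the smallest adjusted p (0.0266), and 1 did at 4 doublings, YCR108C (adjusted p = 0.0265). Among X cores, 10 of 16 had a lower anti-HA change at 1 doubling and 12 of 16 at 4 doublings, with TEL01R-XC at -7.24 ± 0.72 (SE, adjusted p = 6.79e-05).

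Signal also appeared above its control in libraries that the comparisons did not use. In log-phase cells of the second course, anti-HA stood at 12.9 over X cores and at 10.7 over the silencers of HML and HMR. With anti-T7 these values were 0.645 and 0.818. In both log-phase libraries 36.4% of bins were linear and not divided by input. In starved cells of the overexpression strain, anti-HA stood at 12.9 over X cores and at 14.6 over the silencers, against 0.913 and 2.0 after 2 doublings and 0.752 and 0.503 after 12 doublings in dextrose. No starved library without induction is at hand, and after 1 h in dextrose the values were 5.21 and 8.36.

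tRNA genes gained anti-T7 signal in both courses, with a median over 1 to 4 doublings of 1.04 in the second. In that course the untagged anti-T7 library of log-phase cells, with 36.4% of bins at exactly 0, stood 0.59 above that of starved cells, so a background of growing cells that needs no T7 tag may account for part of the gain. In the first course the gain of anti-T7 exceeded that of anti-HA by 2.75, with 97.0% of 234 tRNA genes over 0.2, which argues against the input that the 2 libraries of a point share, while in the second course it was -0.25 and leaves that input open. In the first course 5 other genes of RNA polymerase III had a median of 16.2 against 1.28 for 72 snoRNA genes, a ratio of 12.6, so the signal may be tied to this polymerase, although RNA170 had 0.462 against 0.542 before the switch. Anti-T7 at the silencers was 4.86 to 19.6 times its level before the switch over the silencers measured in both libraries, which argues against another protein in place of Sir3-T7, while a mixture with another immunoprecipitate, such as one with the anti-TAP antibody that the protocol also names, stays open.

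Ribosomal protein genes gained anti-HA signal after release, with a median of 0.43 over 1 to 4 doublings in the second course. The untagged anti-T7 library of log-phase cells, with 36.4% of bins at exactly 0, was 0.26 above that of starved cells over these genes, so a background of growing cells that needs no epitope tag may account for part of it. Anti-HA in log phase was 0.44 above that in starved cells. In that log-phase anti-HA library 36.4% of bins were linear and not divided by input. A shared input alone would leave a tag-by-time difference of 0. The value at 4 doublings was 0.13 (adjusted p = 0.00202, but adjusted p = 0.414 with an estimated correlation), so the anti-HA gain cannot be told apart from an effect of that input.

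The number of genes called in anti-HA at 30 min depended on how the libraries were weighted. With log2 bins only or the deposited scores as they stand, few or no calls were left either. The weights therefore do not single out unequal noise as the cause. With weights estimated per library, both anti-HA libraries at 30 min had a weight of 0.140, and 1 gene of 400 was called. The median SE of the 400 went from 0.32 to 0.54, so unequal noise of the libraries may account for the calls. The median absolute log2 change stayed at 1.31. Both libraries of a group had equal weights here, so weighting could not move it, and whether noise enlarged the changes stays open. Genes called lower were short (median 770 bp against 1190 bp for all genes). Whether old Sir3 left or entered any of these genes stays open, and no biological explanation was tested.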

How the results depend on the processing

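Of the alternatives in this part, the deposited scores as they stand, log2 bins only, all annotated features, genes of at least 300 bp, library weights, each run alone, tag differences within a point, the first 1 kb and lists without the first-course 30 min libraries were chosen after seeing the data. Where a result changed, the cause was not tested.

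For anti-HA against anti-T7 before the switch, 0 genes became 1 without division by the library median and with a pseudocount of 0.5. The count was also 1 in the 400 bp upstream, with the deposited scores, with library weights and with tag differences within a point. With log2 bins only it was 2. Among all annotated features 46 passed, of which 1 was a protein-coding gene. For anti-HA at 4 doublings, 0 genes became 2 without division by the median, with a pseudocount of 0.5, the deposited scores and library weights. The count was 1 in the 400 bp upstream, with run 1 alone and with run 2 alone, and 3 with log2 bins only. Among all annotated features 44 passed, of which 2 were protein-coding genes. For anti-HA at 1 doubling, 0 genes became 2 with log2 bins only. Among all annotated features 25 passed, 1 higher, which was a protein-coding gene, and 24 lower. For anti-T7, 0 genes became 2 at 30 min with the deposited scores and 1 at 4 doublings with log2 bins only. Among all annotated features 12 passed at 1 doubling and 4 at 4 doublings, of which 0 were protein-coding genes.

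For anti-HA at 30 min, 400 genes became 1769 with the median of bins (183 higher, 1586 lower), 0 with the deposited scores by limma (561 at an unadjusted p under 0.05), 2 with log2 bins only and 1 with library weights. Without the course as a block, which pairs the libraries of a course, 233 passed, all among the 400, and the block changed no other count of genes, while X cores called went from 3 to 1 in anti-T7 at 1 doubling, from 1 to 0 in anti-HA at 30 min and from 10 to 9 at 1 doubling. The count stayed near the main one without division by the median (389, of which 37 higher and 352 lower), in the 400 bp upstream (527, of which 56 shared) and for genes of at least 300 bp (362). In the 400 bp upstream 8 named genes changed sign: CCW12 (-0.20), YBR072C-A (0.0069), TIM8 (0.50), RPP0 (-1.38), COX13 (0.72), HXT1 (-0.74), FUS3 (-0.60) and YNR071C (-0.11). With the deposited scores YGL041C-B (0.37) and YFL019C (0.25) did.

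Leaving out 1 library at a time, with the lone library of a group assumed to vary like the others, gave 14 to 1707 genes for anti-HA at 30 min, 0 to 1 for anti-T7 at 30 min, anti-T7 at 1 doubling and anti-HA at 4 doublings, and 0 to 0 for the others.

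For galactose against dextrose, 3 genes became 5 with the median of bins, 39 in the 400 bp upstream (0 shared), 12 with the deposited scores, 17 with log2 bins only, 33 without the 1 h point and 0 without 2 doublings by limma (410 at an unadjusted p under 0.05). Library weights were not run there. Raffinose against dextrose gave 0 under every alternative.

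With an estimated correlation 10 of 55 list tests passed, 9 upward and 1 downward. Without the first-course 30 min libraries, highly transcribed genes in anti-T7 at 30 min (adjusted p = 0.950) and glycolysis genes between 30 min and 4 doublings (adjusted p = 0.695) changed sign. For anti-HA against doublings in the second course, r was -0.526 for 20 kb (permutation adjusted p = 0.363), -0.490 with the mean over genes (0.170), -0.805 without the 2 farthest libraries (0.15) and -0.494 for the first 1 kb (0.126). There rho was -0.488 (0.454), -0.903 (0.0107), -0.880 (0.1) and -0.903 (0.0107), and -0.683 for 5 kb (0.1). In the first course r was -0.678 for 5 kb (0.0451), and rho lost its call for 20 kb (-0.736, 0.0554) and without division by the median (-0.229, 0.818).

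Of 49 called genes named over their alternatives, 503 values were the same, 256 lost their call with the same direction and 10 changed sign. X core counts ranged over alternatives from 11 to 12 before the switch, 0 to 3 for anti-HA at 30 min, 5 to 11 for anti-HA at 1 doubling, 11 to 13 at 4 doublings, and 0 to 5 for anti-T7 at 1 and at 4 doublings. As the tables hold no counts, what depth limits could not be measured.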

Other observations

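The test of dilution in this part was chosen after seeing the results, and that of the splits of libraries before. Anti-T7 at the silencers of HML and HMR in the first course stood at 4.45 after the switch and 7.84 at 2 h after it in starved cells, then at 1.85 and 2.69 at 30 and 90 min after release, and at 19.3 at 1 doubling. Over X cores the same libraries had 2.21, 5.35, 1.24, 1.21 and 2.56. Each is a single library, and the difference was not tested. In the second course anti-T7 at the silencers stood at 1.41 at release and 2.03 at 30 min.

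The 16 centromeres had a median log2 difference of -3.17 between galactose and dextrose in the overexpression strain, from -4.66 to -1.18, and none passed. Against dextrose, raffinose gave a median of -0.95. Genes more than 30 kb from an end that reached 2 times the median gene numbered 394 after the switch, 328 at 2 h after it and 569 at 30 min with anti-HA in the first course, against 13 before the switch. With anti-T7 they numbered 290, 7 and 23 at these points. At 30 min in the second course they numbered 271 with anti-HA and 27 with anti-T7, and in its log-phase cells, which carry no T7 tag, 566 with anti-T7. In the first course 8.98%, 24.6% and 53.8% of bins held exactly 0 with anti-HA at these points, and 3.23%, 0.316% and 1.61% with anti-T7. In the second course the share was 10.6% with anti-HA at 30 min and 36.4% with anti-T7 in log phase. Whether the counts reflect Sir3 or such bins was not tested.

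Anti-HA at X cores fell faster than by 1 doubling alone. The excess over the median gene left at 1 doubling was 0.0169 of that before the switch in the first course and 0.0938 in the second, where dilution by the first doubling alone would leave 0.5, which argues against dilution as the whole cause. At 30 min, 0.492 and 0.475 of the excess was left. Measured from the last anti-HA library before or at release (2 h after the switch in the first course, 0 min in the second), which stood higher than before the switch, 0.371 and 0.316 was left at 30 min and 0.0128 and 0.0625 at 1 doubling. Whether old Sir3 was lost from the cell or only from these elements stays open, as no protein level was measured.

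Of the ways to split the 6 galactose and dextrose libraries into equal groups, 10 splits are too few for a share under 0.05. The real split gave 3 genes and the highest other 1.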
